A study of Rattus norvegicus with 10 samples.

How the data were processed

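Gene expression was measured in the livers of 10 male rats aged 13 weeks, with 1 array for each liver. Per the labels' protocols, biotin-labelled cRNA was made from 100 ng of total RNA of each sample, and the extraction text speaks of brain while the samples are labelled liver. The probe set identifiers are those of an Affymetrix rat genome array. The deposited table holds 1 log2 signal per probe set and array, and neither its header nor the labels name the summary or normalization method, which is not given in the sources used here. The base of the logarithm was read from the values, which run from 4.79 to 14.34 and would exceed what a scanner can record on a natural or decimal log scale. Array medians lay between 6.47 and 6.48. Since 86.2% of probe sets hardly varied within the groups (SD under 0.001 log2 units), these medians do not show whether the levels of the others had been aligned. Detection calls and scanner intensities were not used here, so that no depth can be given and the number of arrays limits the precision.

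Of 31099 probe sets, 57 controls were left out of the tests. The platform's gene table assigned 20826 probe sets to exactly 1 gene and 436 to several, and 9780 were unnamed in it. Symbols were updated by gene identifier through the gene table of the GRCr8 assembly, which matched 20764 of the probe sets with 1 gene. That table served for names only, and no coordinates are given because the files name no genome build. The probe set with the highest mean over the 10 arrays stood for each gene, which left 14217 genes, 4525 of them with more than 1 probe set. No filter on dim probe sets was applied. Within the groups, 86.2% of probe sets had an SD under 0.001 log2 units. Over all arrays 11604 genes (81.6%) had an SD at or under 0.01, and 2613 had a larger one. Those 2613 genes are called the varying genes, and the rest near-constant.

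The 5 livers of the seasoned diet were compared with the 5 control livers using limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with no covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes were called at an adjusted p under 0.05. The titles number the animals separately, so that the p-values measure the spread between rats. A total of 36 gene lists, 24 of pathways and 12 of cell type markers, was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry (its directional and mixed p) were run beside it. The comparison, the lists, the alternatives listed below as chosen in advance, and the rule for named genes were fixed before the data were examined. The rule took the 8 genes with the smallest p in each direction where fewer passed, the 3 members with the smallest p of each list, and a fixed set of lipid, gluconeogenic and growth hormone genes. Npas2, Cry1, Nfil3, Nr1d1, Nr1d2, Per3, Bhlhe40, Tef, Usp2, Sqle, Idi1, Insig1, Insig2, Stard4, Cdkn1a, Alb, Tarbp1, Rnf125, C8h15orf39, Ankrd44, Hsd17b2, Cish, Kynu, Srsf4, Cd163 and C1qc are named outside this rule, after their values had been seen.

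A clock score was formed per liver as the mean of 5 varying genes of the clock list (Bmal1, Clock, Npas2, Cry1 and Nfil3) minus the mean of its 10 other varying genes, each relative to the control mean. This grouping was written after the directions of the genes had been seen and follows their signs in all 15, so the score was also tested with the genes grouped anew by sign in every assignment of the livers. The cholesterol score was the mean of the 18 varying genes of that list. Group differences in scores were tested with an exact two-sided permutation test over 252 assignments, whose smallest possible p is 0.00794. Relations between scores within the diets used exact permutation within the groups, and again within the 4 cells of diet and animal-number set.

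The labels give each sample a code of a letter and a number, which was read here as the row and position of its array. By this reading all seasoned livers were in row A and all control livers in row B, so that row and diet cannot be told apart. Alternatives chosen in advance were a filter on dim probe sets, other probe set rules, repeated quantile normalization, median centring, other variance models and tests, animal number and array position as covariates, an assumed pairing of animals, and leaving out each array. Added after seeing the data were fits on varying genes alone, lists without shared members, and a block for animals 1 to 7 against animals 8 to 14, the place among 7 tried along the animal numbers that gave the most genes. The fits were tested on simulated data for this comparison with 14217 genes, 200 of them changed, all drawn from the varying genes. The recovery given here therefore does not hold for near-constant genes. The main test recovered 35% of genes changed by 0.5 log2 units, 84.5% of those changed by 1 and 97.5% of those changed by 2, with 9, 7 and 10 false calls. Restricted to varying genes, the fit recovered 62%, 95% and 99.5%. For simulated lists over 14217 genes, camera recovered 5 of 5 shifted lists with 0 false calls among the 36. The simulated genes were independent of one another, as the preset correlation nearly assumes. In the livers the estimated correlation was 0.45 for the cholesterol list and 0.39 for the ribosomal list. The simulation therefore does not give the rate of false calls for lists of correlated genes. It also held no difference between animals 1 to 7 and animals 8 to 14, so its false calls do not measure those of the gene test in these livers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.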

Results

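The series asks how the seasonings of an instant noodle diet bear on the liver transcriptome. Rats received a diet with 30 wt% instant noodle and 26% of its energy as fat for 30 days, or the same diet without seasonings. Both groups were fed about 60 g per kg body weight and day in a paired feeding scheme under a cycle of 12 h light and 12 h dark. There were 5 livers per diet. The seasoned animals were numbered 1, 4, 7, 10 and 13, and the controls 2, 5, 8, 11 and 14. Pairwise correlations between arrays lay between 0.990 and 0.998, and 0 pairs of arrays held identical values. These correlations cover all probe sets, 86.2% of which had an SD under 0.001 within the groups, so they say little about the varying genes.

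The deposited values fell into a near-constant and a varying class of genes. Of the 14217 genes, 280 (1.97%) had an SD between 0.001 and 0.05. Albumin (Alb), the main plasma protein made by hepatocytes, was near-constant at 14.34 in every liver, and so was Fgf21, a hepatic fasting hormone, at 6.97. A near-constant gene can reach a small p with a difference that has no measurable size. Pim2, Sult1b1, Naif1 and Pbrm1 were among the genes with the smallest p in their direction, with log2 differences of 0.00019, 0.00026, -0.0012 and -0.00030. Rnf8 (0.42 ± 0.06), Lnx2 (0.62 ± 0.11), Ccdc50 (0.26 ± 0.05), Vegfa (-0.25 ± 0.04) and Tspan12 (-0.21 ± 0.04) were varying genes among them, and without a block none of these 5 passed over all genes or among the 2613 varying genes of the 10 livers.

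**Figure D1:**
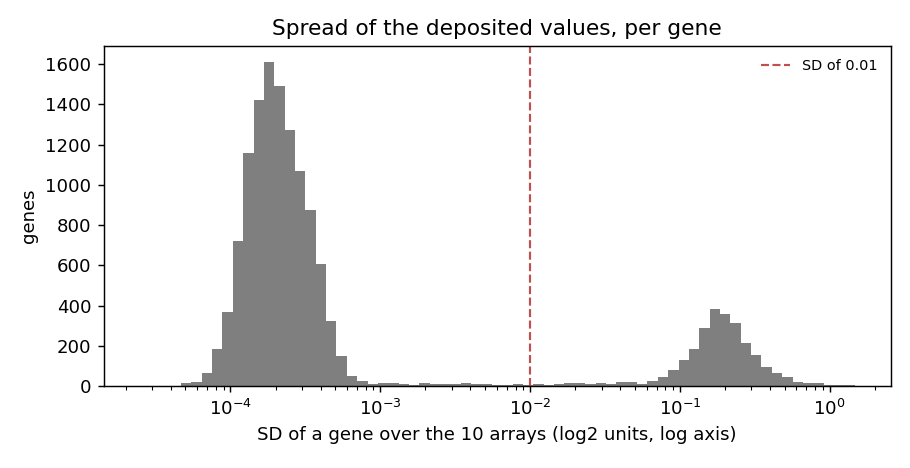
Histogram of the SD of each of the 14217 genes over the 10 arrays (log2 units, logarithmic axis; the vertical axis counts genes). The dashed line marks an SD of 0.01, with 11604 genes at or under it and 2613 above it.

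Among the varying genes, 3 rose and 1 fell with the seasoned diet. Slc6a6, the taurine transporter, rose 2.70-fold, with a log2 difference of 1.44 ± 0.18 (SE, 5 livers per group) and an adjusted p of 0.0246 by limma. Tubb2a, a beta-tubulin, rose 2.92-fold (1.55 ± 0.22, adjusted p = 0.0264) and Lgalsl, a galectin-like protein, rose 1.97-fold (0.98 ± 0.14, adjusted p = 0.0264). Klf9, a transcription factor gene induced by glucocorticoids and thyroid hormone, fell by 0.93 ± 0.14 on the log2 scale (adjusted p = 0.0398). In each of these 4 genes all seasoned livers lay on the same side of all control livers. In all 4, the control nearest the seasoned livers was animal 11, whose clock genes also resembled theirs (below). It was at 7.85 for Slc6a6, 9.48 for Tubb2a, 7.44 for Lgalsl and 9.76 for Klf9. A share of the clock difference in these 4 calls was not tested. A second probe set had the same sign for Slc6a6 (1.22) and Lgalsl (0.60), as did 1 further varying probe set of Klf9 (-0.39).

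The restriction to varying genes was chosen after seeing the data, so the 4 calls rest on that choice. Over all 14217 genes limma called 0 genes, with a smallest adjusted p of 0.431. At an unadjusted p under 0.05 there were 669 genes (420 higher and 249 lower with the seasoned diet), against 711 expected by chance. Among the 2613 varying genes the unadjusted count was 316 (177 higher, 139 lower), against 131 expected. Other tools over all genes gave 0 calls with Welch's statistic (562 at an unadjusted p under 0.05), 1 with array weights and 539 with the rank product. Leaving out control animal 11 gave 5 calls over all genes, namely Slc6a6, Kynu, Srsf4, Tns2 and Dbp. Among varying genes the count of 4 went to 52 without control animal 11, 16 without seasoned animal 10, 8 without control animal 2, 6 without seasoned animal 13 and 2 without control animal 8. It went to 0 without seasoned animals 1, 4 or 7, or without control animals 5 or 14. The groups did not overlap in 71 varying genes (2.72%) and in 54 near-constant genes (0.465%), where chance gives 0.794%. Over all 14217 genes the count was 125 (0.879%), close to the chance share.

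The animals with lower and higher numbers differed from one another more than the diets did. Animals 1 to 7 (3 seasoned, 2 control) and animals 8 to 14 (2 seasoned, 3 control) differed in 1476 of all genes by limma, of which 934 were near-constant. In a fit of the varying genes alone, 780 differed, 717 of them lower in animals 8 to 14. This parting was found in the data, as the one with the most genes of 7 tried along the animal numbers, and the labels name no batch that follows it. Within each diet, however, the array positions rise with animal number, so that animals 8 to 14 hold the later positions of each row. With the animal-number set as a block, 12 varying genes were called between the diets, 9 higher and 3 lower. Higher were Lgalsl, Slc6a6, Tarbp1, Rnf125, Rnf8, Lnx2, C8h15orf39, Tubb2a and Ankrd44. Lower were Nedd9, a scaffold of integrin signalling, Klf9, and Errfi1, a feedback inhibitor of the EGF receptor. Over all genes the block gave 0 calls and 828 genes at an unadjusted p under 0.05. The blocked log2 difference was 1.46 ± 0.19 for Slc6a6, 1.53 ± 0.24 for Tubb2a, 0.95 ± 0.12 for Rnf125, a ubiquitin ligase, and -0.66 ± 0.08 for Nedd9. Within animals 1 to 7 and within animals 8 to 14, Slc6a6 differed by 1.62 and 1.30, and Klf9 by -0.94 and -0.87.

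The genes of the circadian clock separated the diets in both directions. Of 18 measured members, 3 rose and 7 fell when adjusted over the list alone, and 0 passed over all genes. The 3 were the activators Bmal1 (log2 difference 1.14 ± 0.21), Npas2 (1.02 ± 0.24) and Clock (0.37 ± 0.07). The 7 were the output factors Dbp (-2.46 ± 0.46) and Tef (-0.61 ± 0.16), the repressors Nr1d1 (-0.96 ± 0.30), Nr1d2 (-1.06 ± 0.22), Per3 (-1.05 ± 0.25) and Bhlhe40 (-0.79 ± 0.18), and the deubiquitinase gene Usp2 (-0.97 ± 0.32). Dbp, a PAR bZIP transcription factor with a strong daily rhythm, was at 6.39 ± 0.56 (SD) in seasoned livers and 8.84 ± 0.88 in controls. Its seasoned level lay under the array medians, as did those of Per3 (6.38) and Usp2 (6.37) and the control level of Bmal1 (6.33). No fold is given for these genes, and the size of their log2 differences is uncertain for the same reason. Cry1 and Nfil3, which did not pass within the list, differed by 0.44 ± 0.17 and 0.59 ± 0.27.

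Camera called the clock list as lower with the seasoned diet at an adjusted p of 0.00024, with adjusted p = 0.308 with an estimated correlation. Its median log2 difference was -0.40. The clock score, whose grouping of genes follows the signs of their differences, was higher by 1.66 in seasoned livers (5 livers per group). With the genes grouped anew in every assignment of the livers, 6 of 252 gave a score difference as large (exact permutation p = 0.0238). The difference lay between 1.54 and 1.94 with any 1 liver left out. With the animal-number block the difference was 1.59 (exact within-set permutation p = 0.03, also with the genes grouped anew). It was 2.37 within animals 1 to 7 and 0.81 within animals 8 to 14. Control animal 11 had a clock score of 1.12, among the seasoned animals at 0.97 to 2.15, while the other controls lay between -0.45 and -0.17. Its Dbp signal was 7.28, against 9.08 to 9.43 in the other controls. Without this animal the score differed by 1.94, and by 1.29 within animals 8 to 14.

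**Figure D2:**
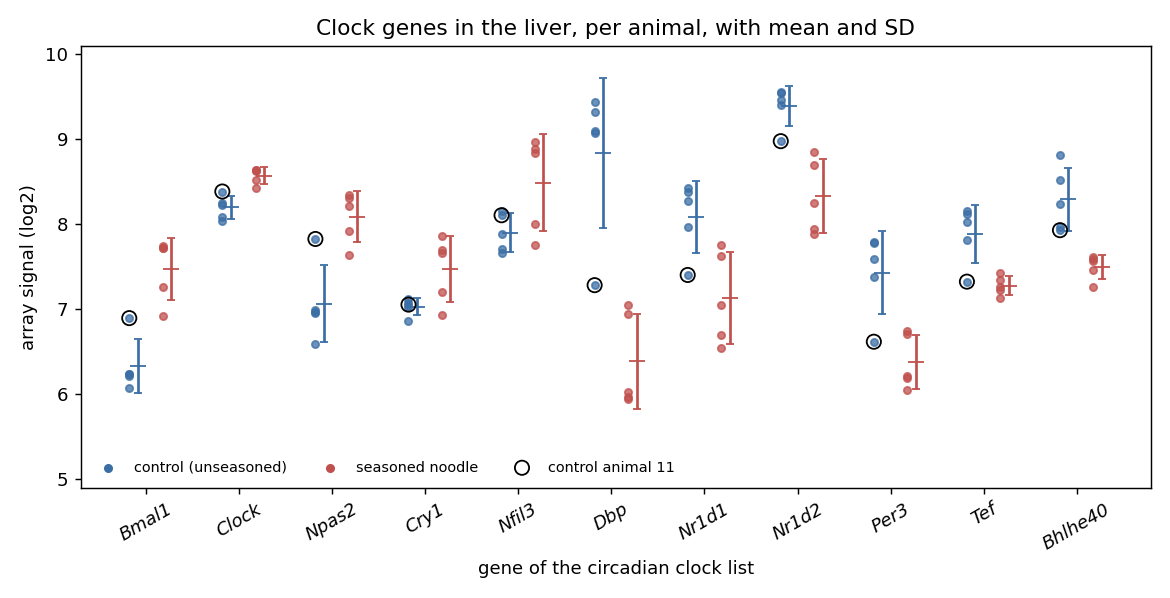
Array signal (log2) of 11 genes of the clock list in each liver, as points, with the mean and SD of each group beside them (5 livers per diet). Control animal 11 is circled; for Dbp it lies at 7.28, between the other controls at 9.08 or above and the seasoned livers at 7.05 or below.

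Genes of cholesterol synthesis had higher signals with the seasoned diet in 19 of 20 measured members, with a median log2 difference of 0.31. Fdps, which makes farnesyl diphosphate, rose by 0.53 ± 0.12 when adjusted over the list alone (adjusted p = 0.0385 by limma), and 0 members passed over all genes. It was at 10.62 ± 0.20 (SD) in seasoned livers and 10.09 ± 0.19 in controls, with no overlap. Further members had differences of 0.70 ± 0.20 (Cyp51, lanosterol demethylase), 0.61 ± 0.18 (Lss, lanosterol synthase), 0.73 ± 0.30 (Sqle, squalene epoxidase) and 0.67 ± 0.24 (Idi1). Stard4, a cholesterol carrier, had the only negative difference in the list at -0.18 ± 0.20. Insig1, a sterol-responsive regulator, differed by 0.27 ± 0.38, with -0.15 within animals 1 to 7, 0.54 within animals 8 to 14 and 0.53 without control animal 2.

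Camera called this list as higher with the seasoned diet at an adjusted p of 1.99e-11, and the adjusted p = 0.308 with an estimated correlation. The cholesterol score differed by 0.38 (exact permutation p = 0.0397, 5 livers per group), and by 0.34 with the animal-number block (exact within-set permutation p = 0.05). It differed by 0.23 within animals 1 to 7 and by 0.45 within animals 8 to 14. Over the 10 livers, centred on their diet's mean, animal number and cholesterol score had a Pearson r of -0.778 (exact within-group permutation p = 0.0183, adjusted p = 0.0917 over 5 relations, the smallest of them, with the others at 0.744 or above) and a Spearman rho of -0.788, or -0.792 with ranks centred within the diets (exact permutation p = 0.0169). Without the 2 animals farthest from the median number, r was -0.689. Centred on diet and animal-number set, r was -0.711 (exact permutation p = 0.0972, adjusted p = 0.486 over 5 relations), and -0.503 without 2 animals, so the relation was not established within the sets.

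**Figure D3:**
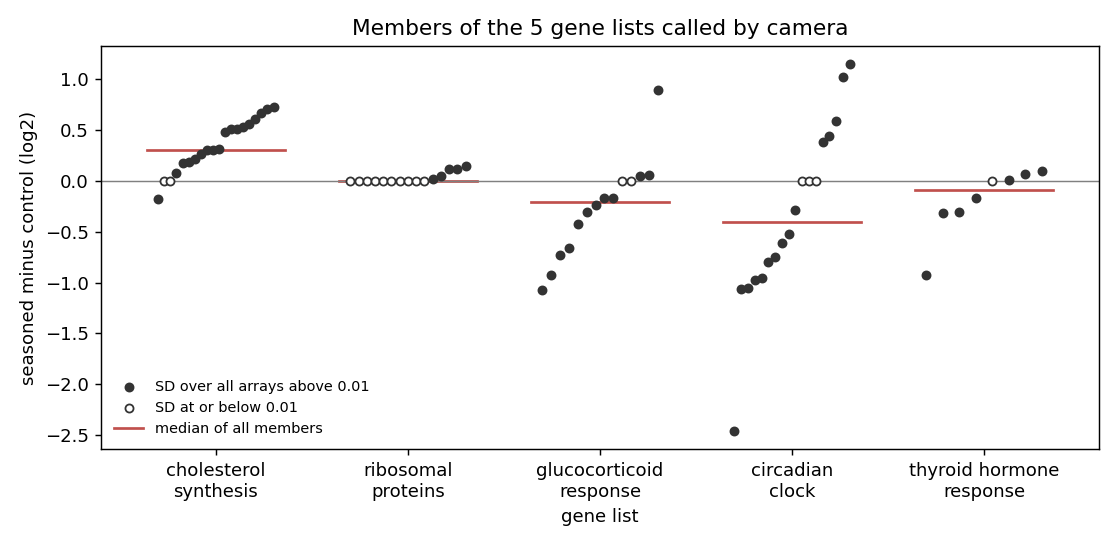
Log2 difference (seasoned minus control) of every measured member of the 5 lists called by camera, each point a gene, ordered within its list. Filled points are varying genes, open points near-constant ones, and the red line is the median of the list; 19 of 20 cholesterol genes lie above 0, while 10 of 15 ribosomal protein genes are near-constant at about 0.

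**Figure D4:**
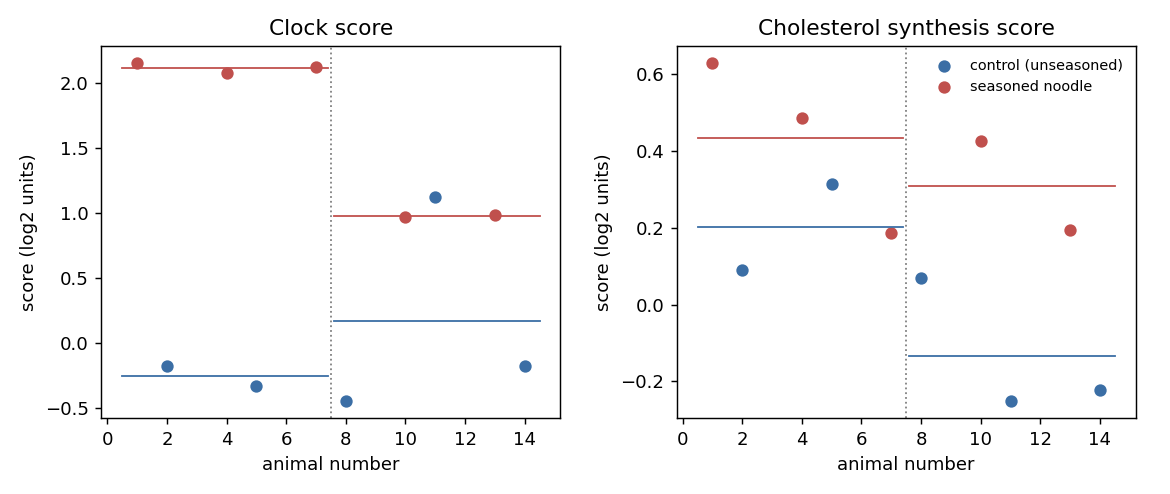
Clock score and cholesterol score (log2 units, relative to the mean of the controls) of each liver against animal number, with lines at the mean of each diet within animals 1 to 7 and within animals 8 to 14. Control animal 11 has a clock score of 1.12, and the cholesterol score is highest in seasoned animal 1 at 0.63.

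Members of the glucocorticoid response list had lower signals with the seasoned diet in 10 of 14 cases. Klf9 fell when adjusted over the list alone. Errfi1 differed by -0.66 ± 0.20 and Mt2A, a metallothionein, by -1.07 ± 0.41, neither passing within the list, while Cdkn1a, a cell cycle inhibitor, had a difference of 0.89 ± 0.43. Camera called the list as lower (adjusted p = 3.12e-05), with adjusted p = 0.0800 with an estimated correlation. The mean of its 11 varying members other than clock genes and Klf9 differed by -0.25 (exact permutation p = 0.0397, 5 livers per group). With the animal-number block this difference was -0.24 (exact within-set permutation p = 0.07), with -0.18 within animals 1 to 7 and -0.30 within animals 8 to 14.

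The thyroid hormone response list shares Klf9 and Pck1 with the glucocorticoid list. Klf9 fell when adjusted over the list alone, and Thrb, a thyroid hormone receptor, differed by -0.31 ± 0.10. Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase, differed by -0.17 ± 0.07. Camera called the list of 8 genes as lower (adjusted p = 0.00704), with adjusted p = 0.474 with an estimated correlation. Without Klf9 the adjusted p was 0.136, with the animal-number block 0.0525, with an assumed pairing of animals 0.0634, and without control animal 2 it was 0.0882.

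The ribosomal protein list was called as higher by camera (adjusted p = 1.69e-08), with adjusted p = 0.308 with an estimated correlation, and all 15 measured members had positive differences in the deposited values, while after repeated quantile normalization Rpl7 and Rpl19 differed by -0.0028 and -0.019. Of these 15, 10 were near-constant, and the median log2 difference was 0.00015. Rpl11 had a difference of 0.12 ± 0.03, while Rpl7 and Rpl19 differed by 0.00014 and 0.00015. Among varying genes alone the list, with 5 members left, was not called (adjusted p = 0.175).

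Genes of fatty acid metabolism did not pass singly or as lists. Scd, the stearoyl-CoA desaturase, differed by -0.49 ± 0.24, Fasn, fatty acid synthase, by 0.27 ± 0.50, and the lipogenic regulator Srebf1 by 0.10 ± 0.32. Within animals 1 to 7 and animals 8 to 14 Fasn differed by -0.62 and 1.22, and Srebf1 by -0.48 and 0.69. Without seasoned animal 13 both differed by -0.09, and without control animal 8 Srebf1 differed by -0.08. The fatty acid synthesis list had an adjusted p of 0.886 by camera, and fatty acid oxidation one of 0.823, both tested as lower with positive mean and median differences. Cpt1a, which admits fatty acids to mitochondria, differed by -0.48 ± 0.15, Plin2, a lipid droplet coat protein, by 0.41 ± 0.15, and Ppara, the fatty acid receptor, by -0.11 ± 0.09. Apoa1, the main protein of high-density lipoprotein, differed by 0.23 ± 0.07 and did not overlap between groups. Gpam, the first enzyme of triglyceride synthesis, differed by 0.23 ± 0.05. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -0.31 ± 0.54, with -1.44 within animals 1 to 7 and 0.98 within animals 8 to 14. Sds, serine dehydratase, had the largest difference among amino acid genes at -2.03 ± 0.46.

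No cell type list was called. The hepatocyte list had a median level of 13.6 and an adjusted p of 0.851, and the brain list had a median level of 6.14 and an adjusted p of 0.874. In both, the test pointed lower while the mean difference was above 0. The macrophage and Kupffer cell list had an adjusted p of 0.236 and the periportal hepatocyte list one of 0.0592, with Sds at -2.03 and Hal, another periportal enzyme, at 0.18 ± 0.13 (-0.06 and 0.32 within the animal-number sets). Among pathway lists, oxidative phosphorylation (adjusted p = 0.0539), the renin-angiotensin and osmotic list that holds Slc6a6 and the antioxidant response (adjusted p = 0.0592 each) lay nearest above the threshold. No list was called by fry's directional test, in which the glucocorticoid list had the smallest adjusted p at 0.0608. Its mixed test called 5, namely the glucocorticoid, clock, thyroid, cholesterol and renin-angiotensin and osmotic lists. The last, at a mixed adjusted p of 0.00065 by fry, was not called by camera, and the ribosomal list was not called by the mixed test (adjusted p = 0.109).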

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

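The tests of an offset common to the genes of an array row, of unequal clock time, of array handling and RNA degradation, of the animal-number sets as the source of the cholesterol difference, and of other splits for the genes called after adjustment were chosen after the result had been seen. The clock score, its grouping of genes by their direction and the cholesterol score were also formed then. The criteria of the RNA degradation test and of the animal-number test on cholesterol genes were made stricter after their values had been seen, which left both explanations open where the earlier criteria had excluded them.

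Among 168 groups of 5 livers (82 genes and 2 scores, each in both diets), 18 held a liver whose gap to its nearest neighbour was over 0.71 of the group's range. Chance flags about 1 in 20 groups, or 8.4 here if the groups were independent. Some of the genes were named after their values had been seen, and the clock genes also enter the clock score. The excess over 8.4, and the flags of any 1 animal, therefore cannot be weighed against chance. Control animal 11 stood apart most often. It was high for Slc6a6 (ratio 0.8356), Bmal1 (0.8058) and Cdkn1a (0.8365), and low for Dbp (0.8336), Tns2 (0.7302), Nr1d2 (0.7474), Ppara (0.8498), Herpud1 (0.7934), Hsd17b2 (0.7898), Srsf4 (0.7112) and Usp2 (0.7765). It also held the high clock score of the control group (0.8248). Control animal 2 was high for Rnf8 (0.7106) and Pnpla3 (0.7159), and control animal 8 was low for Ccdc50 (0.7622). Seasoned animal 1 was high for Fdps (0.7147), seasoned animal 10 low for Lnx2 (0.7288) and seasoned animal 7 low for Herpud1 (0.7999).

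The clock difference between the diets was weighed first. An offset common to the genes of an array row or of the normalization moves all members the same way, whereas 3 rose and 7 fell when adjusted over the list alone; effects of the row that differ from gene to gene cannot be told apart from the diet. The labels give no time of killing, so the score difference of 1.66 could equally reflect a different clock time of the groups when the livers were taken, and this cannot be told apart from an effect of the diet. A wrong label of control animal 11 stays open: over genes outside the clock list it lay 0.642 of the way from the other controls to the seasoned livers, but seasoned animals 10 and 13 lay at 0.50 and 0.458, and control animals 2 and 5 at 0.427 and 0.412. A shift of liver clock phase by the seasonings is a hypothesis that these livers do not settle.

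The higher cholesterol synthesis signals do not rest on a single liver, since the lowest difference with any 1 left out was 0.32 against 0.38 with all. With the clock score in the model the difference was 0.50, but it ranged from 0.17 to 0.70 with 1 liver left out, so that a share of the clock difference in it cannot be told apart. Within the diets the 2 scores had r = 0.356 in seasoned and -0.653 in control livers, and pooled over both no relation was seen (r = -0.206, exact within-group permutation p = 0.604, adjusted p = 0.755; rho = -0.164, centred ranks -0.161, exact permutation p = 0.662; r = -0.106 without the 2 farthest animals). Centred on diet and animal-number set, r was -0.401 (exact permutation p = 0.382), in livers too few to exclude a relation. With the animal-number block the cholesterol difference was 0.34, positive within both sets, with an exact permutation p of 0.05. Camera with the block called the list at an adjusted p of 2.06e-09, at the preset correlation of 0.01. The estimated correlation of this list was 0.45, and camera using it without the block did not call the list (adjusted p = 0.308). The small blocked p therefore adds little to the exact one. The block takes out a shift between the sets that is common to both diets, and most of the difference remained. What remained had an exact p not under 0.05, so chance is not excluded for it. By the criterion used, which asked for an exact p under 0.05, the sets were not excluded as a source. The diet itself, as a biological source, was not tested apart from these.

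The split of animals 1 to 7 from animals 8 to 14 points to a structure of the samples beside the diets, and since the sets were drawn from the data their p-values describe them only. A bacterial control transcript (BioC), which is added at hybridization and does not come from the liver, was lower by 0.24 in animals 8 to 14 (log2 difference -0.24, exact permutation p = 0.0159), which is consistent with a difference in array handling; the mean of its 4 probe sets still overlapped slightly between the sets, at 9.18 to 9.19, while 1 of the 4 did not overlap (-0.25, exact permutation p = 0.00794). The probe sets of BioB, another such control, differed by -0.01 and -0.07 (exact permutation p = 0.119 each), so the test does not decide. The beta-actin signal at the 3' end minus that at the 5' end, a sign of RNA degradation, differed by -0.065 (exact permutation p = 0.238), too close to its SD of 0.086 within the sets to settle degradation either way. An order of killing or dissection was not tested, since the labels give none. Array position rises with animal number within each row. An effect of that order of positions cannot be told apart from the order of the animals. The sets are no group of the study, so no biological explanation was tested.

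Other splits of the 10 livers into 5 and 5 do not let chance be excluded for the unadjusted count, for the calls over all genes or for the lists. Of 100 splits drawn, the real one included, 12 gave as many varying genes at an unadjusted p under 0.05 (316, with 1087 as the highest of the other splits). For genes called after adjustment the real count was 0, so that all 100 gave as many, with 1476 as the highest. For the 4 varying genes called after adjustment, 4 of 100 gave as many, with 780 as the highest, and 4 of all 126 possible splits. The highest counts of genes came from the split of animals 1 to 7 from animals 8 to 14, far above the real ones. For called lists 58 of 100 gave as many (5, highest 16), so the number of lists called by camera says little by itself. Within the sets there are 100 arrangements of the diets, and with the block 5 of them gave as many varying genes at an unadjusted p under 0.05 (381, highest other 471), and 74 as many lists (4, highest other 13). The 12 varying genes called with the block were reached by 1 of 100, the real one, with 11 as the highest of the others. For the 4 and the 12 genes the share of splits was thus under 5% within these fits alone. The limit on SD, the block and the use of splits for these counts were chosen after the data had been seen. The splits make no allowance for that choice or for the several counts tried, so chance is not excluded for these genes either. The 4 calls also went to 0 when seasoned animals 1, 4 or 7, or control animals 5 or 14, were left out. The fit fixed beforehand called 0 genes with limma (669 at an unadjusted p under 0.05, 539 by the rank product).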

How the results depend on the processing

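The fits on varying genes alone, the animal-number block, the fit without control animal 11 under that block and the lists without shared members were tests chosen after seeing the data. The count of genes changed, 0 by limma with 669 at an unadjusted p under 0.05, was 1 with array weights (Slc6a6), 539 with the rank product, 4 for genes with an SD over 0.01 and 19 for an SD over 0.05. It was 12 with the animal-number block among varying genes, and 99 there without control animal 11. The rank product made 216 false calls on simulated data with a log2 change of 1. The other settings, among them the filter on dim probe sets, median centring and Welch's statistic on varying genes (260 at an unadjusted p under 0.05), gave 0. With 1 liver left out the count ran from 0 to 5, the 5 without control animal 11; the cause was not tested.

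The count of 5 lists was 9 with the mean of a gene's probe sets, 11 with repeated quantile normalization, 0 with an estimated correlation and 0 by fry, and the cause was not tested. It ran from 5 to 10 with 1 liver left out, with 9 without seasoned animal 4, 8 without seasoned animal 10 and 10 without seasoned animal 13. The cholesterol, clock, glucocorticoid and ribosomal lists were called in each leave-one-out fit, and the thyroid list in 9 of 10. None of these 5 lists turned its direction. The assumed pairing of animals by rank, as a replicate block, gave 0 genes and 6 lists, with the thyroid list not among them (adjusted p = 0.0634). Paired ranks correlated at 0.088, 0.115, -0.034, -0.101 and 0.206, with 2 of 5 ranks closest to their own number, so the animals share an assumed rank at most.

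For 82 named genes over 26 settings, 73 of 2086 values passed the threshold, in the direction reported, and the others stayed on their side of it. Signs differed in 26 of these others, 10 of them of near-constant genes, and 5 of the 26 also moved by more than the spread between livers. Signal over background was not examined, so what it limits is not known here; the values of 11604 genes are near-constant.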

Other observations

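All values in this part were picked after the data had been seen, and no tests were planned for them.

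Onecut1, a hepatic transcription factor, and Bcl6, a repressor that growth hormone lowers in liver, split the control animals. Onecut1 was at 10.49, 10.84 and 10.34 in control animals 8, 11 and 14, and between 7.23 and 8.14 in the remaining livers of both diets. Bcl6 was at 8.29, 7.38 and 6.97 in the same 3 controls and between 9.43 and 10.14 elsewhere. Cish, a feedback inhibitor induced by growth hormone, had a seasoned minus control difference of -0.02 within animals 1 to 7 and -1.81 within animals 8 to 14, and this contrast between the sets was not tested. The growth hormone axis list was not called (adjusted p = 0.973 by camera, tested as lower with a median difference above 0), and Igf1 (0.03 ± 0.06) and the receptor Ghr (-0.01 ± 0.10) had differences near 0. Stat5b, which carries the growth hormone signal, rose by 0.35 ± 0.08 when adjusted over that list alone (adjusted p = 0.0428 by limma). Xbp1, a regulator of the unfolded protein response, followed the same animals, with 11.63, 11.45 and 11.41 in control animals 8, 11 and 14 and 10.37 to 10.94 elsewhere.

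Hsd17b2, which oxidises estradiol and testosterone, was at 10.52 ± 0.72 (SD) with the seasoned diet and 12.31 ± 0.46 in controls, and control animal 11 at 11.52 lay below seasoned animal 10 at 11.59. Its adjusted p among varying genes was 0.0634 by limma. Insig2, an anchor protein of the SREBP pathway, was higher in every seasoned liver than in any control. It differed by 0.52 ± 0.11 (SE), with an adjusted p of 0.0791 among varying genes by limma. Herpud1, a gene of the endoplasmic reticulum stress response, differed by -0.59 ± 0.15, and Sdf2l1 of the same list by 0.28 ± 0.09. Cyp1a2, a xenobiotic-metabolising cytochrome, differed by 0.48 ± 0.16.

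Between the animal-number sets, all 13 measured genes of the macrophage and Kupffer cell list were lower in animals 8 to 14, with a median log2 difference of -0.29 and an adjusted p of 0.000207 by camera, with adjusted p = 0.937 with an estimated correlation. The sets had been picked as the parting with the most differing genes. Clec4f, a Kupffer cell lectin, differed by -0.58 ± 0.09, Cd163, a scavenger receptor, by -0.43 ± 0.10, and C1qc, of complement, by -0.39 ± 0.08. Of all varying genes 75.8% were lower in those animals, with a median difference of -0.14. The brain list was called as higher (adjusted p = 0.0337, and adjusted p = 0.937 with an estimated correlation), with 15 of 16 genes near-constant and a median difference of 0.00018.

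Near-constant genes were examined for the ribosomal list. Ribosomal protein genes among them had a median t statistic of 2.16, against 0.431 for 221 near-constant genes of like signal, and their log2 differences had a median size of 0.00015.

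Further values on the clock score and the animal order were computed. The lowest seasoned clock score was 0.97, against -0.17 as the highest of the controls other than animal 11, so that by this score no seasoned liver lay among those controls. Over genes outside the clock list, seasoned animals 10 and 13 lay at 0.50 and 0.458 of the way to the seasoned livers, close to control animals 2 and 5, which leaves an exchange with control animal 11 open. With animal number in the model the clock score differed by 1.63, and at the lowest by 1.48 with 1 liver left out. Other places to part the animals by number gave at most 268 varying genes by limma, against 780 between animals 1 to 7 and animals 8 to 14.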
